A study of Homo sapiens with 5 samples.

How the data were processed

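Total RNA from MDA-MB-231 cells was measured on 5 single-colour arrays, 3 of DMSO-treated and 2 of SAHA-treated cells. Per the labels, SAHA or DMSO was in the medium for 30 h and the SAHA concentration was 2 uM. The labels' extraction text also mentions a transfection that no other label describes, and the exposure time was taken from the treatment text. Per the labels, RNA was extracted with Trizol, cleaned on a column, amplified and labelled with biotin. Per the submitters' processing notes, values were made with RMA in R 2.12. RMA corrects background, normalizes quantiles across arrays and summarises the probes of each probe set. The deposited values cover 54675 probe sets as intensity values on a linear scale, and the per-array range ran from 4.56 to 38935, so log2 was taken before any test. The design had assumed log2 values and allowed for this step. Values were not normalized again. Quantile normalization makes the arrays' distributions nearly alike, so a shift of all transcripts in one direction is removed before the values are read. The background correction could not be redone from summarised values, and the table has no detection calls, so signal over background is unknown for single probe sets.

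Of the 54675 probe sets, 62 were array controls, 41091 had 1 gene, 1801 had several genes and 11721 had none given in the annotation used here. Symbols were updated through gene identifiers for 41037 of the 41091, and 54 kept the table's symbol. Control probe sets and those with several genes or none were left out of gene tests. The probe set with the highest mean over the 5 arrays stood for its gene, which left 19775 genes with no filter on level. Of 5849 called genes, 3742 had more than 1 probe set. For 1779 of these another probe set was called in the same direction and for 56 in the opposite one. Probe sets whose names end in _x_at or _s_at can share sequence between genes or transcripts and are called shared-sequence probe sets here. Of 485 list members, 429 were measured, and members without a row in that annotation were not analysed here.

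SAHA was compared with DMSO in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no covariates, tables handled with data.table, version 1.17.8), with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p under 0.05. All limma tests were two-sided. The fit had 3 residual degrees of freedom and 1.62 prior degrees of freedom. Some genes had equal values on the arrays of a group, and leaving them out was 1 of the alternatives. Gene lists were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 25 lists and separately over the 6 marker lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera uses the 3 residual degrees of freedom of the fit, so few lists can pass after adjustment. The lists, tests and alternatives of the report and the rule for named genes were fixed before the data were examined. Exceptions, chosen after the values were seen, were centring on the poly-A controls, leaving out genes with equal values, the comparisons of poly-A, ribosomal RNA and hybridisation controls, the tests of the controls and of the level pattern, the gene families and the level-matched random lists. The placental, motile cilia and cornification lists of the closing section were also drawn up after the highest folds were seen, and leave out the genes seen there. The rule named the 10 highest and 10 lowest log2 folds among called genes whose SAHA arrays all lay on one side of the DMSO arrays. It also named up to 4 called members of each list with the largest absolute log2 fold, or the 2 largest where 0 passed, and a fixed panel of genes. IFI6 and OAS1, and the families and cilia genes in the closing section, were named after their values were seen.

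Controls with a mean intensity of 100 or less were left out of the control summaries. These were 3 poly-A and 1 ribosomal RNA probe sets. Alternatives covered scaling (quantile normalization again, centring on ribosomal protein genes, on the median gene or on the poly-A controls), dim genes (below the 40th percentile), the choice of probe set, the variance model, array weights, each array left out in turn, a replicate block, a stricter threshold of 0.01 and an unmoderated test per gene with equal variances. On simulated data for this comparison (19775 genes), 100 genes were given a 2-fold change, 100 a 1.41-fold change and a further list of 20 genes a rise of 0.5 on the log2 scale. Of these, 98%, 72% and 13 of 20 were called with the right sign, and 3.7% of the 190 called genes were not changed. The simulated noise was independent between genes, and only 220 genes were changed in all. Far more genes were called in the real data, so these figures do not carry over to the real calls. Random lists of the closing section (10000 per list) were matched on the mean level over all arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.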

Results

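MDA-MB-231 is a human breast cancer cell line of mesenchymal appearance that lacks the oestrogen receptor. SAHA (vorinostat) is a hydroxamate that inhibits histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. The series asked which genes change expression when these cells are exposed to SAHA. Total RNA was profiled on 5 oligonucleotide arrays with several probes per transcript. There were 3 arrays of cells given the vehicle DMSO and 2 arrays of cells given 2 uM SAHA, all collected after 30 h per the labels. Median intensity per array was 90, 90.3 and 90.1 in DMSO and 88.8 and 91.2 in SAHA. The number of arrays limits the precision, and nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

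The arrays separated by treatment. Across the 19775 genes tested, Pearson's r was 0.9972 to 0.9986 between arrays of the same group and 0.9791 to 0.9801 between groups (genes are not independent replicates). The array DMSO 1 stood apart in the control probe sets for ACTB, the cytoskeletal actin used to judge RNA integrity. Its 3' minus 5' difference was 3.29 on the log2 scale, against 2.08, 2.22, 2.16 and 2.04 on DMSO 2, DMSO 3, SAHA 1 and SAHA 2. Control RNAs also differed between the groups. The 24 probe sets for the Bacillus subtilis polyadenylated control RNAs had a median log2 difference of 0.39 (range 0.17 to 0.66), with both SAHA arrays above all DMSO arrays for all 24. The 5 probe sets for human ribosomal RNA had a median log2 difference of 1.16 (range 0.46 to 1.73). Probe sets of each kind are repeated readings of a few RNAs and are not independent. The 18 probe sets for the hybridisation controls, which enter after labelling, had a median of -0.02 (-0.15 without DMSO 1).

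**Figure D1:**
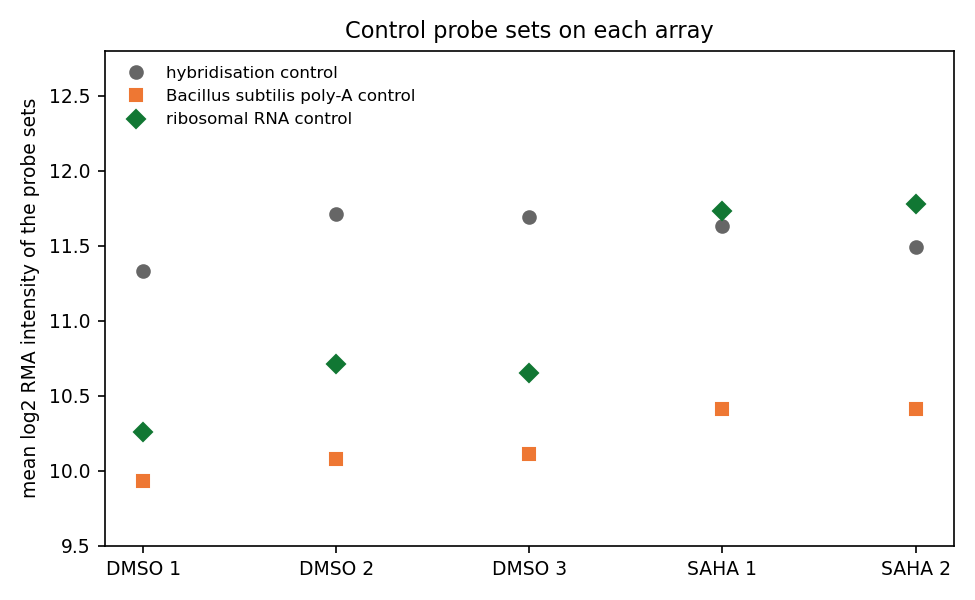
Mean log2 RMA intensity of the control probe sets on each of the 5 arrays, by kind of control, with 1 point per array and kind. The poly-A controls lay at 9.93, 10.08 and 10.11 in DMSO and at 10.41 on both SAHA arrays, and the ribosomal RNA controls at 10.26 to 10.71 in DMSO and 11.73 and 11.78 in SAHA.

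FLG, which encodes filaggrin of the cornified epidermis, had the highest fold after SAHA. It rose 58.8-fold, from a mean log2 intensity of 6.44 ± 0.07 (SD, n = 3) to 12.31 ± 0.15 (SD, n = 2), with a log2 fold of 5.88 ± 0.09 (SE; limma adjusted p = 0.00021). The next highest were ENPP5, which rose 23.4-fold, DHRS2, a short-chain dehydrogenase (15.9-fold), SHOC1, a factor of meiotic recombination (15.5-fold), and FABP4, a fatty acid-binding protein (15.2-fold). INHBA, an activin subunit, rose 14.5-fold, C1orf116 13.8-fold, the cytokine IL24 13.2-fold, LUM, an extracellular matrix proteoglycan, 13.1-fold, and the steroid dehydrogenase HSD3B1 12.1-fold. Limma adjusted p-values of these 9 genes were 0.00021 to 0.00138. The DMSO level of ENPP5 was dim (4.035 ± 0.2, SD, n = 3). The mean DMSO levels of FLG, INHBA, HSD3B1, FABP4 and C1orf116 also lay below the median log2 intensity of each DMSO array (6.492 to 6.497). Signal over background is unknown for single probe sets, so folds from such levels, that of FLG included, are uncertain in size and rank. Without shared-sequence probe sets LUM gave a log2 fold of 2.23 against 3.71. With all probe sets of a gene averaged, the folds of 8 of these 10 genes moved by over 1.5 times.

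SLCO4A1, an organic anion transporter, had the lowest fold. It fell 15.1-fold, from 10.01 ± 0.21 (SD, n = 3) to 6.10 ± 0.11 (SD, n = 2), with a log2 fold of -3.92 ± 0.14 (SE; limma adjusted p = 0.000491). NMI, an interferon-inducible partner of MYC and STAT proteins, fell 7.54-fold, and IGFBP1, which binds insulin-like growth factors, 6.44-fold. TYMS, the enzyme that makes thymidylate for DNA synthesis, fell by 2.62 on the log2 scale from one of the brighter levels of the array (13.26 ± 0.03, SD, n = 3). DRC8 fell 5.95-fold, FAM169A 5.69-fold, the interferon-inducible RSAD2 5.68-fold, the transcription factor IIIC subunit GTF3C6 5.56-fold, the immunoproteasome subunit PSMB10 5.35-fold and the interferon-inducible ligase HERC6 5.28-fold. Limma adjusted p-values of these 9 genes were 0.000341 to 0.00181. With all probe sets of a gene averaged, the folds of 6 of these 10 genes moved by over 1.5 times. SLCO4A1 was among them, with a log2 fold of -1.96, against -2.91 for NMI. The rank of SLCO4A1 as the lowest thus rests on its brightest probe set. Its other probe set was not called in that direction.

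**Figure D2:**
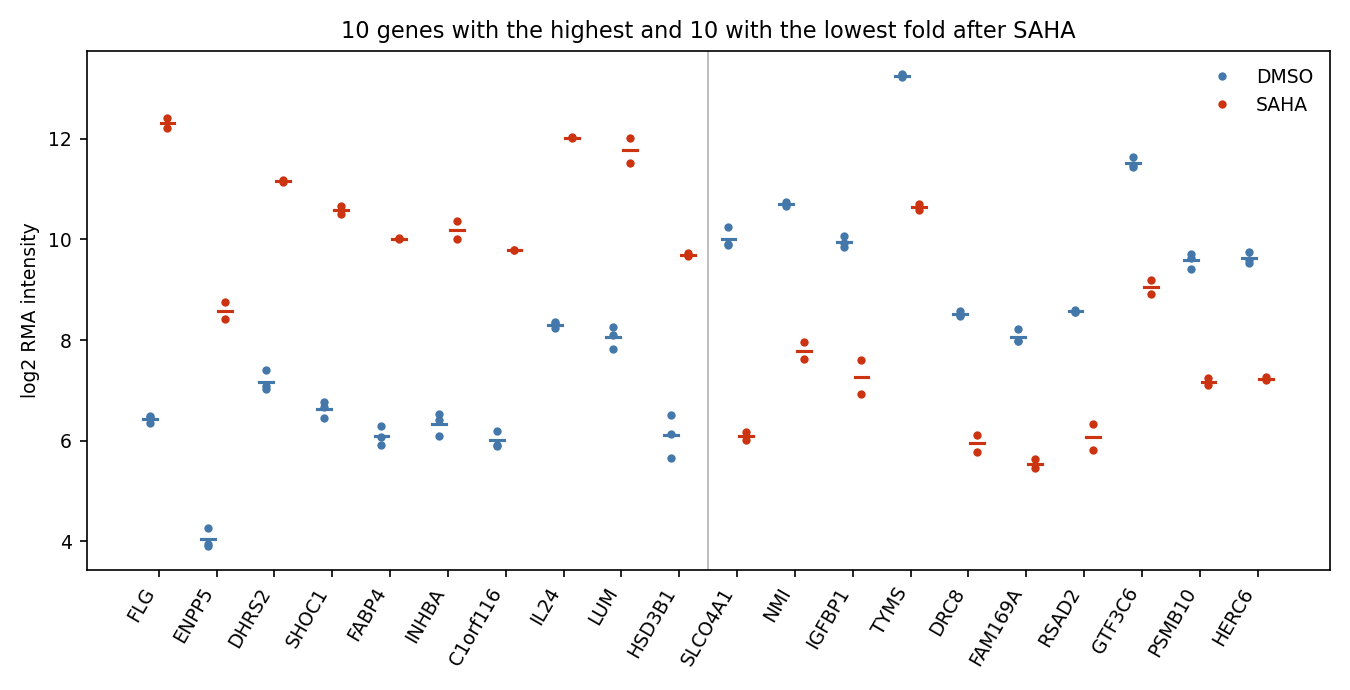
Log2 RMA intensity (y axis) of the 10 genes with the highest and the 10 with the lowest fold, with 1 point per array (3 DMSO, 2 SAHA) and a bar at each group's mean. In each of these genes both SAHA arrays lay on one side of all DMSO arrays, with FLG at 6.44 against 12.31 and SLCO4A1 at 10.01 against 6.10.

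Among the 19775 genes, 2760 were higher and 3089 lower after SAHA by limma at a Benjamini-Hochberg adjusted p under 0.05, which was 29.6% of genes. At least 2-fold changes were called for 635 higher and 502 lower genes, and at least 4-fold changes for 121 higher and 21 lower genes. The share of called genes that rose was 47.2% (95% exact binomial interval 45.9 to 48.5%, across genes that are not independent). Both SAHA arrays lay beyond all DMSO arrays for 9514 of the 19775 genes, an arrangement that chance gives 20% of genes. These included all 5849 called genes, which the test favours for that arrangement. The share that rose depended on scaling. With each array centred on the poly-A controls, an alternative chosen after the data were seen, the median gene lay at -0.40, 1380 genes were called higher and 14740 lower, and 8.6% of called genes rose. Each fit with an array left out has fewer residual degrees of freedom, so a call lost there can also reflect lost power. Without SAHA 1 or SAHA 2 a single SAHA array remains, and the spread comes from the DMSO arrays alone. Without DMSO 1 the counts were 2075 higher and 2353 lower. They were 1834 and 2217 without DMSO 2, 1769 and 1985 without DMSO 3, and 1780 and 2254 without SAHA 1.

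Genes of DNA replication and S phase were lower as a group. All 25 measured members fell (25 adjusted over the list alone), with a median log2 fold of -1.17. Besides TYMS, these included the cyclin CCNE2 (-2.07 ± 0.13, SE), GINS2 of the replicative helicase (-1.93 ± 0.08, SE) and the ribonucleotide reductase subunit RRM2 (-1.72 ± 0.08, SE). For GINS2 the brightest probe set that remained without shared-sequence probe sets gave -0.12 (limma adjusted p = 0.335). Of 23 mitosis genes, 21 fell (21 over the list alone), with a median of -1.06, led by AURKB (-1.48), the proliferation marker MKI67 (-1.48), CCNB2 (-1.46) and KIF20A (-1.33). With probe sets averaged GINS2 gave -0.87 and CCNB2 -0.47. Of 15 genes of homologous recombination and Fanconi repair, 12 fell (12 adjusted over the list alone), with a median of -1.03, among them the helicase BRIP1 (-2.01), RAD51AP1 (-1.64), RAD54L (-1.62) and BRCA1 (-1.29). In limma's camera test with a preset correlation of 0.01, adjusted over 25 lists, these lists gave adjusted p = 1.25e-14, 2.77e-11 and 1.01e-05. With an estimated correlation the adjusted p-values were 0.305, 0.307 and 0.332.

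Interferon-stimulated genes were also lower as a group, but not uniformly. Of 19 measured, 12 fell and 2 rose (14 and 3 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.00104, and adjusted p = 0.305 with an estimated correlation). IFIT2 (-2.09), IFIT3 (-2.05), OASL (-1.94) and IFI44 (-1.91) were the most lowered. The 2 that rose, named here because they went against the list, were IFI6 (1.75 ± 0.11, SE) and OAS1 (0.22 ± 0.05, SE), and 1 member rose without DMSO 2, DMSO 3, SAHA 1 or SAHA 2. Genes of the unfolded protein and integrated stress response were lower too. Of 18 measured, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.0282, and adjusted p = 0.715 with an estimated correlation). TRIB3 (-1.79), DDIT3 (-1.50), the transcription factor XBP1 (-1.37) and ATF4 (-0.89), which drives DDIT3 and TRIB3, fell. With probe sets averaged TRIB3 gave -1.13 and XBP1 -0.78. Without DMSO 2, SAHA 1 or SAHA 2, 0 members rose. The list's call ended without DMSO 2, DMSO 3 or SAHA 2 (camera adjusted p = 0.0542, 0.0536 and 0.122) and without dim genes (0.0605).

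Among the 25 lists, targets of YAP/TEAD and SMAD transcription factors had the highest median. Of 15 measured, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 3.71e-05, and adjusted p = 0.305 with an estimated correlation). ANKRD1 rose 4.8-fold, ID2, an inhibitor of basic helix-loop-helix factors, 4.46-fold, the matricellular protein CCN2 2.67-fold and SKIL 2.16-fold (without DMSO 3, limma adjusted p = 0.0501 for SKIL). With probe sets averaged the log2 fold of ID2 was 1.37 against 2.16 and that of SKIL 0.22 against 1.11. Without SAHA 2, 1 member fell. With centring on the poly-A controls, 8 of this list were called higher and 4 lower, with a median of 0.31.

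Linker and core histone genes, autophagy and lysosome genes, and epithelial genes were called higher in the same test, less firmly. Of 14 histone genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0348, and adjusted p = 0.308 with an estimated correlation). H2BC5 rose 3.72-fold, H4C8 3.31-fold and the linker histone H1-2 2.42-fold, while H2AX, the variant phosphorylated at DNA breaks, fell by 1.11 on the log2 scale. Without SAHA 1, 5 histone genes rose and 2 fell, and without SAHA 2, 4 rose. Of 18 autophagy and lysosome genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.0282, and adjusted p = 0.308 with an estimated correlation). The risen count was 2 without DMSO 1 or SAHA 1 and 3 without DMSO 2 or DMSO 3, and 0 fell without SAHA 1. The autophagosome proteins GABARAPL2 (0.87), GABARAPL1 (0.66) and MAP1LC3B (0.51) rose and the protease CTSL (-0.45) fell. GABARAPL1 lost its call without DMSO 1, DMSO 2, DMSO 3 or SAHA 1 (limma adjusted p = 0.0501 to 0.079) and CTSL without SAHA 1 or SAHA 2 (0.0534 and 0.0587). MAP1LC3B gave 0.14 with centring on the poly-A controls (limma adjusted p = 0.271). Of 22 epithelial genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.0425, and adjusted p = 0.644 with an estimated correlation). CDH1, the epithelial cadherin, rose 3.11-fold from a dim level of 4.67 ± 0.17 (SD, n = 3), and its other probe set was not called in that direction (0.77 on the log2 scale with both averaged, against 1.64). KRT19 (0.94) and KRT7 (0.92) rose and the tight junction gene MARVELD2 (-0.998) fell, and without SAHA 2, 1 epithelial gene fell. KRT19 was no longer called without SAHA 1 or SAHA 2, though its log2 fold was 0.82 to 1.02 with each array left out. KRT7 gave -0.06 without shared-sequence probe sets and 0.29 with its probe sets averaged. The histone call ended without SAHA 1 or SAHA 2 (camera adjusted p = 0.146 and 0.0674) and the epithelial call without DMSO 1, SAHA 1 or SAHA 2 (0.0562, 0.0824 and 0.142), with array weights (0.0561) or with probe sets averaged (0.113). All 3 list calls ended when quantile normalization was run again (camera adjusted p = 0.0516, 0.0699 and 0.067 in the order given), without dim genes (0.0572, 0.0902 and 0.0605) and without shared-sequence probe sets (0.153, 0.143 and 0.273). With centring on the poly-A controls their medians were -0.01, -0.18 and -0.29, and the autophagy call ended (0.183).

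**Figure D3:**
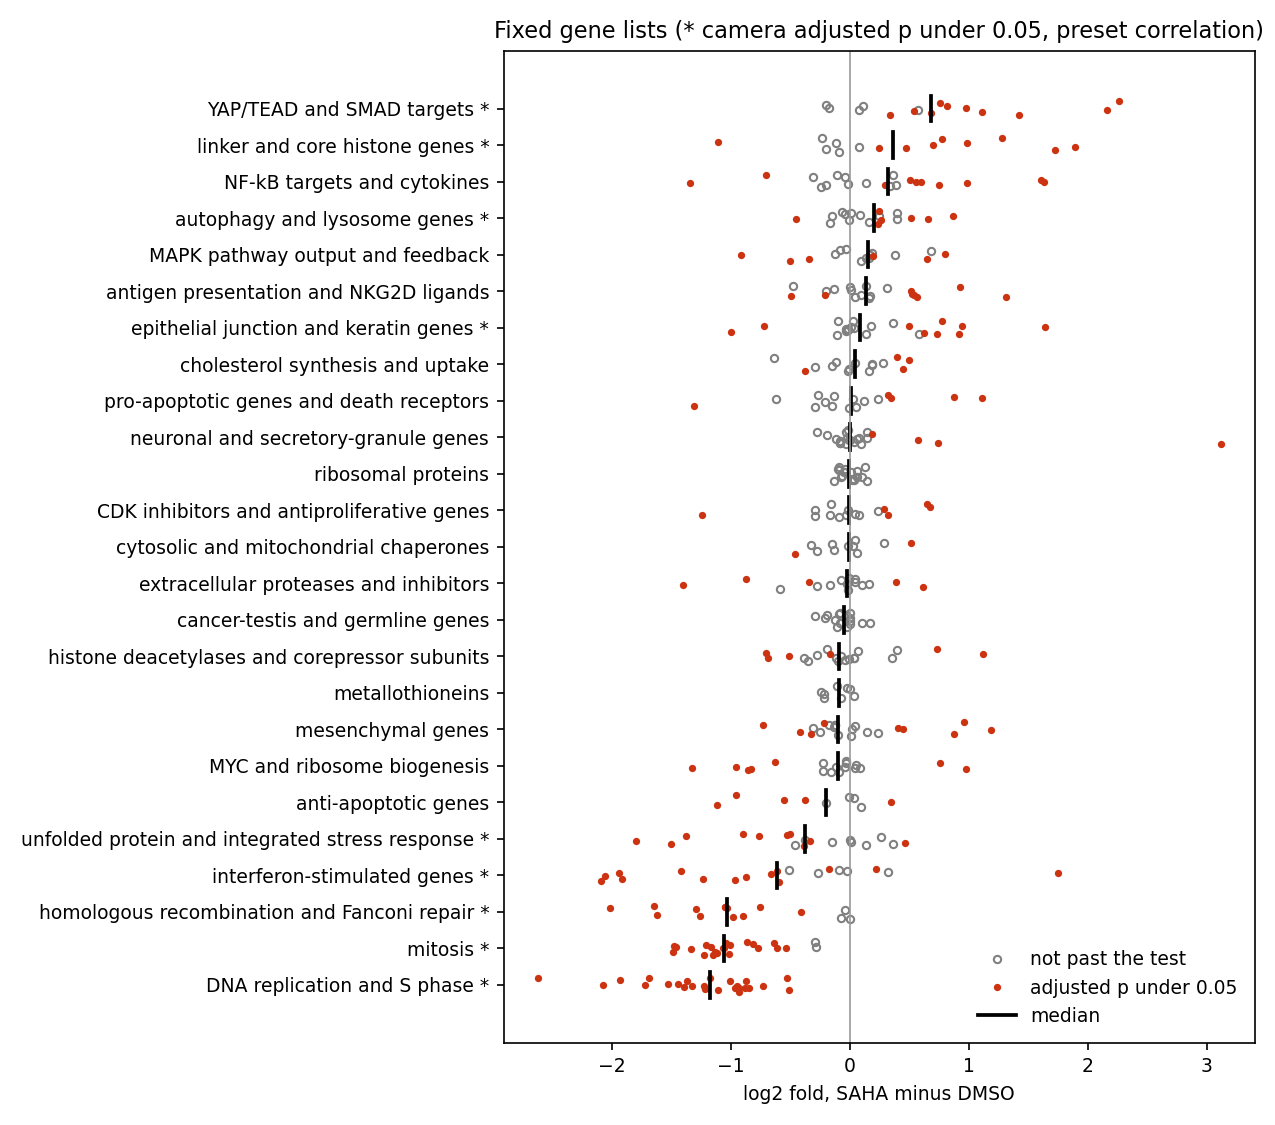
Log2 fold, SAHA minus DMSO (x axis), of each measured member of the 25 gene lists (y axis), with filled points past a limma adjusted p of 0.05, open points not past it and a bar at each median. The list medians ran from -1.17 for DNA replication and S phase to 0.68 for YAP/TEAD and SMAD targets.

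The other 16 lists did not pass the test with the preset correlation. Antigen presentation genes had 6 members that rose and 2 that fell of 19 (6 and 3 adjusted over the list alone, camera adjusted p = 0.0634). The fallen count was 1 without DMSO 1 or DMSO 2 and 0 without DMSO 3, SAHA 1 or SAHA 2. MICA, a stress-induced ligand of natural killer cells, rose 2.49-fold and HLA-DMA, CD74 and HLA-DPA1 of the MHC class II pathway rose by 0.92, 0.56 and 0.54 on the log2 scale (HLA-DPA1 not without SAHA 1 or SAHA 2, limma adjusted p = 0.067 and 0.072). With centring on the poly-A controls CD74 gave 0.19 and HLA-DPA1 0.17 (limma adjusted p = 0.152 and 0.201), and CD74 gave 0.10 with its probe sets averaged (0.263). Of 20 NF-kB targets and cytokines, 8 rose and 2 fell (8 and 2 over the list alone, camera adjusted p = 0.086). Without SAHA 1, 3 rose and 1 fell, and 5 rose without DMSO 1, DMSO 2 or SAHA 2. The list was called higher without DMSO 2 (camera adjusted p = 0.0472) and with centring on the poly-A controls (0.0167), among adjusted p-values of 0.0472 to 0.455 with each array left out. IL1A (1.63), CXCL8 (1.61) and IL6 (0.98) rose and the transcription factor subunit NFKB1 (-1.34) fell. IL1A gave -0.05 without shared-sequence probe sets and 0.79 with its probe sets averaged, and IL6 was not called without SAHA 1 (limma adjusted p = 0.0716).

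Genes of cell survival moved in both directions. Of 16 pro-apoptotic genes, 4 rose and 1 fell (4 and 3 over the list alone, camera adjusted p = 0.554). The death ligand TNFSF10 (1.11) and PMAIP1 (0.87) rose, and BID (-1.31), which links death receptors to mitochondria, fell. PMAIP1 was not called without SAHA 1 (limma adjusted p = 0.0569). Of 9 anti-apoptotic genes, 1 rose and 4 fell (1 and 4 over the list alone, camera adjusted p = 0.416), with lower BIRC5 (-1.12), XIAP (-0.95), BCL2 (-0.55) and BCL2L2 (-0.38). Calls of BCL2 and BCL2L2 ended without DMSO 3 (limma adjusted p = 0.0691 and 0.0559) and also without DMSO 2 (0.0596 and 0.0534). BCL2 was also lost without DMSO 1 (0.0593), and BCL2L2 with its probe sets averaged (0.0534). With each array left out in turn, 1 to 3 pro-apoptotic genes rose and 1 to 2 fell, and 2 to 4 anti-apoptotic genes fell (2 without DMSO 2 or DMSO 3).

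Among CDK inhibitors and antiproliferative genes, 4 of 15 rose and 1 fell (4 and 1 over the list alone, camera adjusted p = 0.431). GADD45A (0.68) and TXNIP (0.65) rose and CDKN1C (-1.24; -0.41 with its probe sets averaged) fell. With each array left out in turn 2 to 3 of this list rose and 1 to 3 fell. CDKN1A, the cell cycle inhibitor p21, was 0.32 ± 0.08 (SE; limma adjusted p = 0.0388), and its call ended with each array left out in turn (adjusted p = 0.0602 to 0.129). Of 20 histone deacetylases and corepressor subunits, 2 rose and 4 fell (2 and 4 over the list alone, camera adjusted p = 0.693). HDAC5 (1.12) and HDAC3 (0.73) rose, MTA3 (-0.71) and RBBP4 (-0.68) fell, and HDAC6 fell by 0.51. RBBP4 and HDAC6 each lost their call with 4 of the 5 arrays left out in turn (limma adjusted p up to 0.11 and 0.147), and 1 to 3 of the list fell with each array left out in turn. HDAC1 was 0.03 and HDAC2 0.36 (limma adjusted p = 0.741 and 0.089). Of 18 MYC and ribosome biogenesis genes, 2 rose and 5 fell (2 and 5 over the list alone, camera adjusted p = 0.221). MYC rose 1.97-fold, while UTP20 (-1.32), SRM (-0.96) and CAD (-0.86) fell. MYC was not called without SAHA 1 or SAHA 2 (limma adjusted p = 0.0749 and 0.0517), and 0 of its list rose in either fit.

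In the mesenchymal list 5 of 21 rose and 4 fell (5 and 4 over the list alone, camera adjusted p = 0.714), with higher TGFBI (1.19), ITGA5 (0.96) and TNC (0.87) and lower LOX (-0.72; not without DMSO 2, DMSO 3 or SAHA 2, limma adjusted p = 0.064, 0.0769 and 0.0787). VIM, vimentin, was -0.13 (limma adjusted p = 0.133). In the neuronal list 4 of 22 rose and 0 fell (2 and 0 over the list alone, camera adjusted p = 0.355). SCG2, a secretory granule protein, rose 8.67-fold. SYT11 (0.74), SYT1 (0.57) and SYP (0.19) lost their calls with 4, 4 and 5 of the 5 arrays left out in turn (limma adjusted p up to 0.0744, 0.201 and 0.125). Of the MAPK genes 3 of 16 rose and 3 fell (4 and 3 over the list alone, camera adjusted p = 0.484), with lower FOSL1 (-0.92) and higher DUSP5 (0.65). Of the proteases and inhibitors 2 of 16 rose and 3 fell (2 and 3 over the list alone, camera adjusted p = 0.728), with lower ADAM8 (-1.41; -0.75 with its probe sets averaged) and PLAU (-0.87) and higher MMP3 (0.61). Of the cholesterol genes 3 of 15 rose and 1 fell (3 and 1 over the list alone, camera adjusted p = 0.427), with higher DHCR7 (0.45). With centring on the poly-A controls SYT1 gave 0.20, MMP3 0.24 and DHCR7 0.07 (limma adjusted p = 0.146, 0.0661 and 0.573). Of the chaperones 1 of 11 rose and 1 fell (1 and 1 over the list alone, camera adjusted p = 0.971), with lower HSPD1 (-0.46), which gave -0.21 without shared-sequence probe sets (limma adjusted p = 0.331). Several of these small counts moved with each array left out in turn. Then 2 to 3 mesenchymal genes fell, 1 to 2 neuronal genes rose and 0 to 2 fell, 1 to 2 MAPK genes rose, and 1 to 4 proteases and inhibitors rose. Of the cholesterol genes 1 to 4 rose and 0 to 2 fell, and of the chaperones 0 to 1 rose and 1 to 3 fell.

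For 3 lists 0 members passed limma's test over all genes and 0 over the list alone. The 8 metallothioneins included MT1E (-0.24) and MT2A (-0.22), the 16 germline genes MAEL (-0.29) and SYCP3 (-0.21), and the 18 ribosomal protein genes RPL27 (0.14) and RPL11 (0.13). Camera adjusted p-values were 0.416, 0.724 and 0.869. With 1 array left out, 1 metallothionein fell without DMSO 2, 1 germline gene fell without SAHA 1 and 1 rose without SAHA 2, and 1 ribosomal protein gene fell without DMSO 1. Camera's direction differed from the sign of the median for the CDK inhibitors and the mesenchymal genes (medians -0.01 and -0.10) and from the median and mean for the ribosomal proteins (-0.01 and -0.01). With an estimated correlation 0 of the 25 lists were called. For the interferon and the YAP/TEAD and SMAD lists that correlation was -0.021 and -0.01, below the preset 0.01. A higher correlation between genes thus did not end these 2 calls. This version of camera uses the 3 residual degrees of freedom of the fit, so a lost call there does not show that correlated members made it. Limma's fry, which asks only whether a list's own genes move on balance one way, called 15.

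Of the remaining genes chosen in advance, EGFR, the epidermal growth factor receptor, rose by 0.66 ± 0.07 (SE; limma adjusted p = 0.00353), and gave 0.24 with its probe sets averaged (adjusted p = 0.102). The death receptor TNFRSF10B was 0.35 ± 0.08 (SE; limma adjusted p = 0.0285), and its call ended without DMSO 1, DMSO 2, DMSO 3 or SAHA 1 (adjusted p = 0.0689 to 0.112) and with its probe sets averaged (0.138). The log2 folds of ESR1 (-0.03), CCND1 (0.17), BCL2L1 (-0.01), BCL2L11 (-0.15), KRT8 (0.58) and TUBB3 (-0.004) had limma adjusted p-values of 0.655, 0.149, 0.935, 0.293, 0.0694 and 0.99. A dimmer probe set of BCL2L1 was called higher.

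None of the 6 marker lists of other cell types was called by camera with the preset correlation (adjusted p = 0.233 to 0.412, unadjusted p = 0.0683 to 0.412). With an estimated correlation 0 of 6 were called too. Fry called the leukocyte list lower and the endothelial list higher (fry adjusted p = 0.0192 for each). Of 12 luminal breast markers 2 rose and 1 fell, with ERBB3 at 1.61 (0.61 with its probe sets averaged) and ELF3 at 0.73, and of 7 basal markers 2 rose and 1 fell, with SFN at -0.94. Of 10 fibroblast markers 1 rose (LUM) and 1 fell (COL1A2, -0.38). Without shared-sequence probe sets COL1A2 gave -0.39 but was not called (limma adjusted p = 0.163). Of 8 leukocyte markers 1 rose (CD14, 0.87) and 3 fell, with LAPTM5 at -0.97. Of 7 endothelial markers 2 rose and 0 fell, with KDR at 1.14, and of 5 melanocyte markers 2 rose and 0 fell, with MITF at 0.79. Adjusted over the list alone the counts were the same except that 3 basal markers rose. Calls of CD14, MITF and ELF3 ended with at least 1 array left out (limma adjusted p up to 0.0674, 0.055 and 0.0963). With each array left out in turn the risen counts were 1 to 3 luminal, 1 basal, 1 to 2 fibroblast, 0 to 1 leukocyte, 1 to 2 endothelial and 0 to 2 melanocyte markers. The fallen counts were 0 to 1 luminal, 1 basal, 1 to 2 fibroblast, 1 to 3 leukocyte, 0 to 1 endothelial and 0 melanocyte markers.

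Genes that rose and genes that fell were read at different intensities in DMSO. Level here means intensity, which also depends on the probes of each probe set and does not measure RNA amount across genes. Level was read on DMSO 3 and the calls came from a fit of the other 4 arrays, so that the same noise did not enter both. The 1769 genes called higher had a median log2 level of 8.75 and the 1985 called lower a median of 9.86. The gap was wider for larger changes. The 610 genes that rose at least 2-fold had a median log2 level of 7.74, and the 477 that fell at least 2-fold a median of 9.89. With the genes divided into 3 equal parts by level, 152 genes of the lowest part rose and 5 fell at least 2-fold (96.8% rose). In the middle part 283 rose and 121 fell (70.0%), and in the highest part 175 rose and 351 fell (33.3%). Of all called genes the share that rose was 83.9, 54.6 and 37.6% in the lowest, middle and highest part. No test across genes was made.

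**Figure D4:**
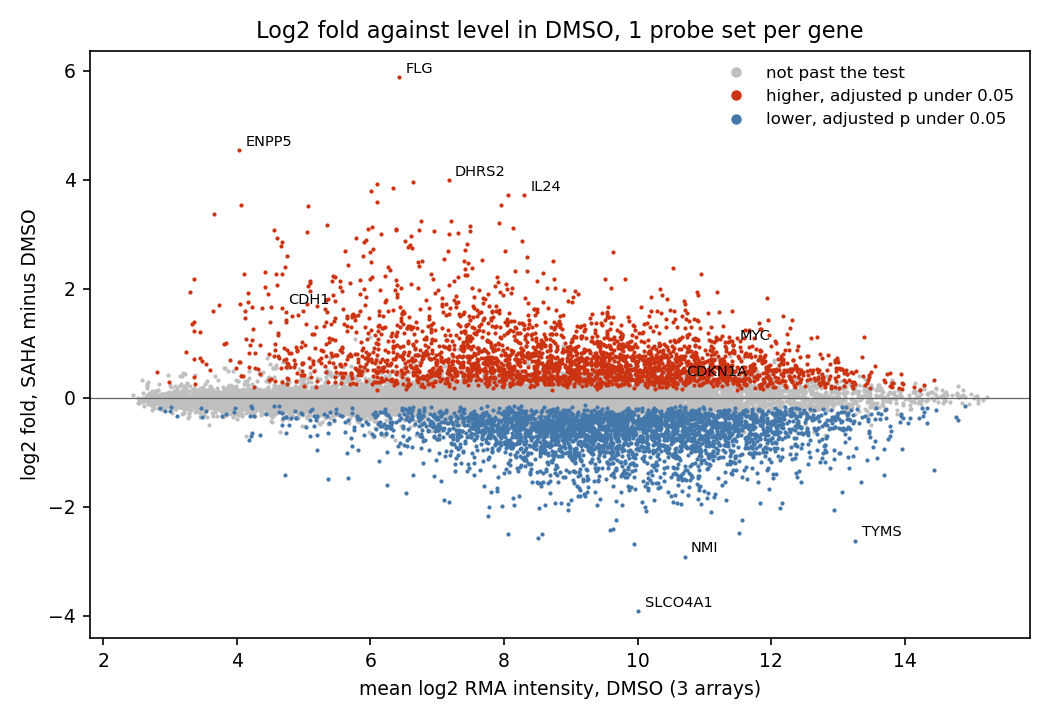
Log2 fold, SAHA minus DMSO (y axis), of each of the 19775 genes against its mean log2 RMA intensity over the 3 DMSO arrays (x axis), coloured by the limma call. Large increases lay mostly at low to middle levels, with FLG at 6.44, and large decreases at middle to high levels, with SLCO4A1 at 10.01 and TYMS at 13.26. Because both axes use the DMSO arrays, the levels quoted for the 3 parts come from an array held out of the calls.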

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

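The tests of the controls and of the level pattern here were chosen after the values were seen. The count over other splits of the arrays was planned and appears last.

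The controls drew attention because they are outside the gene tests. Higher values in SAHA were read for the Bacillus subtilis poly-A control probe sets, by a median of 0.39 on the log2 scale, in 24 of 24 with both SAHA arrays above all DMSO arrays (0.31 without DMSO 1), and for the ribosomal RNA controls, by 1.16 (5 of 5; 1.08 without DMSO 1). These counts are repeated readings of a few RNAs and not independent evidence. The hybridisation controls had a median difference of -0.02. They do not test a brighter scale of the SAHA arrays as a whole, since quantile normalization removes such a scale before any control is read. More complete 5' ends as the whole cause were argued against by the 3' probe sets of the poly-A controls, at 0.25. For the poly-A controls, less cellular mRNA per control molecule and unequal addition of control RNA cannot be told apart. The labels do not say how much control RNA each sample received. The median gene, at -0.40 after centring on the poly-A controls, does not decide. RMA holds that gene near 0 and the value restates the control difference, so whether SAHA lowered mRNA per cell stays open. The ribosomal RNA controls read human RNA, which unequal addition of control RNA would not raise. The cause of their difference was not tested.

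The second pattern was that dim genes mostly rose and bright genes mostly fell among those changed at least 2-fold. A floor on dim genes or a ceiling on bright ones stays open. The share that rose was 67.0% at log2 levels of 7 to 9 (95% exact interval 61.6 to 72.0%) and 34.4% at 9 to 11 (29.7 to 39.4%), a difference of 32.6 percentage points. It was 95.9% below 5, 95.4% at 5 to 7, 31.5% at 11 to 13 (23.7 to 40.3%) and 7.7% above 13 (0.2 to 36%). The intervals at 9 to 11 and 11 to 13 overlapped, and the shares below 9 were higher than those above. These intervals count genes as independent, which they are not, and do not measure the spread between arrays. Without detection calls it is unknown how many genes at 7 to 9 were read at background. Compression of folds in shared-sequence probe sets was argued against, since without them the share that rose still differed between the lowest and highest of 3 equal parts by level by 58.8 percentage points. Whether SAHA itself acts by expression level was not tested, and intensities of different probe sets do not rank genes by RNA amount.

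Among the 11721 probe sets with no gene given, 126 rose and 61 fell at least 2-fold by limma, which marks them as unread signal. Of the 1801 probe sets with several genes, 34 rose and 34 fell at least 2-fold.

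With 5 arrays there are only 10 splits into 3 and 2, so a share under 0.05 cannot be reached. The real split changed 5849 genes, 1 of 10 splits changed as many, and the highest of the others changed 0. Each other split puts SAHA and DMSO arrays in the same group, so any treatment difference enters the spread within groups. Few calls in those splits were therefore nearly fixed in advance, and the count does not decide about chance.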

How the results depend on the processing

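Of the named genes that passed the test (122 of 137), 117 kept their sign in all alternatives in which they were scored. In those, 77 stayed past the threshold in all but the replicate block and the unmoderated test. Genes with several probe sets were not scored where each probe set was tested. Genes with shared-sequence probe sets only were not scored where these were left out. Over all alternatives 2460 gene values stayed on the same side of the threshold, 252 fell short, 27 newly passed and 6 reversed. For lists 460 values stayed, 32 fell short and 8 newly passed. A reversal was counted only where the main or the alternative fit passed the threshold. Sign changes of values that passed in neither are thus among those that stayed. With centring on the poly-A controls, chosen after the data were seen, CDKN1A gave -0.05, TNFRSF10B -0.03, SYP -0.18 and HDAC1 -0.34, 1380 genes were higher and 14740 lower, 325 and 1404 at least 2-fold, and 8.6% rose. That centring adds one offset to all genes of an array, and the prior degrees of freedom were 41.6 against 1.62. Their separate effects on the counts were not tested. Without shared-sequence probe sets KRT7 gave -0.06 and IL1A -0.05, because another probe set stands for the gene. The share that rose was 50% with centring on ribosomal protein genes, 49.1% with probe sets averaged, 50.8% without shared-sequence probe sets, 49.8% with each probe set tested and 45.6% with the unmoderated test. Averaging left 289 genes lower at least 2-fold, and testing each probe set gave 4522 higher, 1127 of the risen ones at least 2-fold, among more features. At adjusted p under 0.01, 1544 were higher and 1773 lower, and with the unmoderated test 1541 and 1836. The replicate block on 4 arrays gave 1262 and 1316 (49% rose), against 1769 and 1985 for the same arrays without a block. The numbers share no label that pairs them, and the correlation of DMSO 1 minus DMSO 2 with SAHA 1 minus SAHA 2 was 0.056. With each array left out, 1769 to 2234 genes were higher and 1985 to 2797 lower, and 44.1 to 47.1% rose. Lists higher numbered 1 when quantile normalization was run again, 1 without dim genes, 1 without shared-sequence probe sets, 2 to 5 with each array left out and 8 by fry. With an estimated correlation 0 were higher and 0 lower. Among genes changed at least 2-fold, the median level of risen minus fallen genes was -2.03 when read on DMSO 2, against medians of 7.74 and 9.89 on DMSO 3. Except where stated, the cause was not tested. The arrays give no depth, and signal over background is unknown.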

Other observations

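Gene families named by their symbols were picked after the highest folds were seen, so only counts of their members are given, with no test of a family. Of 9 measured pregnancy-specific glycoprotein genes, 8 rose, with log2 folds from 2.33 for PSG1 to 3.06 for PSG9 and PSG11 at 0.22. These genes have near-identical sequences and most of their probe sets are of the shared kind, so which of them rose is uncertain and the 8 are not independent. Of 15 MHC class II genes and pseudogenes, 7 rose and 0 fell, led by HLA-DMB (1.88), HLA-DPB1 (1.68) and HLA-DQB1 (1.63), with HLA-DRA at 0.53. Median log2 folds of the 2 families were 2.69 and 0.24. With centring on the poly-A controls they were 2.32 and -0.13, and 5 class II genes were called higher and 5 lower. Of 14 genes with MCM or GINS symbols, which overlap the replication list and include the MCM-binding protein MCMBP, 12 fell and 0 rose. Of 20 claudins 3 rose and 1 fell. The other groups were taken by the start of the symbol and are not limited to coding members of the family. Of 25 genes with integrin symbols 4 rose and 2 fell, with the integrin-like ITGBL1, which is not a subunit, among the risen. Of 18 genes and pseudogenes with tubulin symbols 4 rose and 4 fell, with the pseudogene TUBA3FP among the fallen. Of 31 genes and pseudogenes with serpin symbols 6 rose and 2 fell, and of 56 with histone symbols, pseudogenes and an antisense RNA included, 13 rose and 2 fell. In the order claudins, integrins, tubulins, serpins and histones, these counts became 2 and 15, 4 and 15, 1 and 14, 4 and 23, and 7 and 39 with that centring. CLDN1 was the highest claudin, at 2.41.

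The tests in this paragraph were written before their results were seen, except the comparison with level-matched random lists, but the 3 gene lists were prompted by genes seen among the highest folds. Placental and trophoblast genes, without the genes already seen, gave a camera adjusted p of 0.746 in the downward direction, with a median log2 fold of -0.06. Of 35 measured 5 rose and 4 fell, and the risen share of 14.3% compares with a mean of 9.4% in 10000 random lists matched on level, 95% of which held 0 to 7 risen genes. Motile cilia genes had adjusted p = 0.169 and a median of 0.04. Of 35 measured 8 rose, led by ROPN1L (2.67) and RSPH1 (1.42), and DNAH2 fell (-0.73). The risen share was 22.9%, against a mean of 7.8% and 0 to 6 genes in 95% of matched lists. DRC8, which shares its symbol stem with the listed DRC1 and DRC3, was not in the list. It fell by 2.57 on the log2 scale (0.90 with its probe sets averaged). Cornification genes without FLG gave adjusted p = 0.746 in the downward direction and a median of -0.03 (2 of 34 rose and 0 fell, with 5.9% risen against a mean of 5.8% in matched lists). The comparison written in advance was with the 14% of all genes that rose, and only the cornification genes lay below it. They were mostly dim, with a median level percentile of 18.7, so that comparison was set by level. None of the 3 lists met the rise as a class written in advance, a camera adjusted p under 0.05. The matched lists could not show a shortfall, since their range began at 0 risen genes for each list. Log2 folds of neighbouring genes at least 10 kb apart with different symbol stems correlated weakly across 9957 pairs (Pearson's r = 0.071, against a highest value of 0.034 in 1000 shuffles). The difference of DMSO 2 and DMSO 3 in the same pairs gave r = 0.033, so part of this correlation may be technical. Genes are not independent replicates.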
